A study of Mus musculus with 21 samples.

How the data were processed

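RNA was measured in 21 libraries of cultured mouse breast cancer cells, 3 in each of 7 groups. Per the labels, all derive from E0771 cells that carry GFP. The groups were the untreated parental line E0771GFP, the same line with an empty vector, the line overexpressing ZBTB18, that overexpressing line with a doxycycline-inducible TGFBR2 and given either vehicle or TGF-β1, and a pair of lines, M11GFP (M11) and M12GFP (M12), recovered from spontaneous lung metastases. Per the labels, cells grew in RPMI 1640 with calf serum, the receptor groups received doxycycline (1 mg/mL as the label gives it) with TGF-β1 (2 ng/mL) or vehicle, and polyA-enriched RNA went into a stranded mRNA library kit. Groups and replicate numbers were read from the sample titles, and 0 columns were left unmapped. The labels name no sequencing batch, no length of treatment and no statement that the replicates were separate cultures.

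The authors deposited expected counts per gene, made by RSEM and not normalised, and TPM, which RSEM scales for effective gene length and to a fixed sum per library. Per the submitters' processing notes the tools were Trim Galore, STAR 2.7.1a, GATK 4.1.2.0 and RSEM with genome build mm10; the order of the steps and the annotation release are not stated. The deposited FPKM file was not used here. The table held 55573 genes, of which 99.14% had an identifier in GENCODE vM21, the annotation used here for positions. It also held 92 spike-in entries with 0 reads, which were left out, and 1.28% of its values were not whole numbers, as RSEM shares reads that map to several genes; counts were rounded. Levels of genes with close relatives, such as the clustered protocadherins, histones, and the Oas, Gbp and Ifi families, depend on that sharing.

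Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the package's filter on low counts by group, which left 15432 genes, and a quasi-likelihood F-test with robust spread in a model with 1 mean per group over all 21 libraries (14 residual degrees of freedom). Tests were two-sided, and p was adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Levels are CPM, the library-scaled read counts of edgeR after TMM, given as mean ± SD of 3 libraries. A log2 fold change is written for the first group minus the second. Its SE was derived as its absolute value divided by the square root of the F statistic. Where a group had 0 reads for a gene, the fold is a lower bound against 3 counts over the group; where it had 1 to 3 reads, the ratio of reads per scaled library carries an exact 95% conditional binomial interval. These bounds cover counting error only, since reads were summed over the libraries of a group and variation between replicates is left out. The libraries also carry no molecular identifiers.

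There were 7 comparisons: ZBTB18 overexpression against empty vector, TGF-β1 against vehicle, M11 and M12 each against the parental line, M11 against M12, empty vector against parental, and vehicle against ZBTB18 overexpression without the receptor. Before the data were examined, 35 gene lists were written from general knowledge, none of them from these samples: TGF-β response genes, TGF-β and BMP pathway components, ID family and other ZBTB18 neural targets, epithelial, mesenchymal, matrix, protease, integrin, contractile, sterol and fatty acid synthesis, interferon-stimulated, MHC class I, cytokine and growth factor, cell cycle, p53 target and CDK inhibitor, hypoxia and glycolysis, NRF2, unfolded protein and ATF4, heat shock, immediate early, YAP, Wnt, Notch, chromatin regulator, axon guidance, metastasis-related, mammary lineage, ZBTB family, blood and immune cell, endothelial, fibroblast, lung epithelial, mitochondrially encoded, ribosomal protein and oxidative phosphorylation genes. Each list was tested with camera in limma 3.58.1 with a correlation between genes estimated from the data, adjusted over the lists of a comparison, and with a preset correlation of 0.01 and with fry beside it. The number of members past the threshold is given over all genes and adjusted over the list alone.

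The genes named were chosen by a rule fixed before the data were examined. It took Zbtb18, Tgfbr2 and Tgfbr1 in every group. In each comparison it took genes past the threshold with a fold of at least 2, a mean of at least 5 CPM in the higher group, no overlap between the groups' libraries and an official name: the 8 highest and 8 lowest fold changes in the first 4 comparisons, and 4 and 4 in the others. It took up to 4 members of each list, with all members of the pathway component and ID lists, and the 6 genes with the largest product of fold changes in each overlap. Some genes that the rule selects are not reported here.

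Alternatives were DESeq2 1.42.0 as test or as source of size factors, limma-voom, no filter and a filter of 1 CPM in 3 libraries, the 6 libraries of a comparison alone, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block over all groups, and each library left out in turn; a replicate block within the 2 groups compared was added after the data had been seen. Overlaps were set against the number expected from independent calls, with Fisher's exact test across genes, which are not independent replicates. The edgeR test was checked on simulated data in which 67 or 66 of 15432 genes were changed at each of 3 sizes in the layout of 3 of the comparisons. It recovered 58.2 to 68.7% of 1.5-fold changes, 86.6 to 92.5% of 2-fold changes and 93.9 to 100% of 4-fold changes, and 3.37 to 7.95% of its calls were false. The simulation changed far fewer genes than most comparisons called, and only genes with a mean of at least 1 CPM. It also gave every group the same spread, which the real groups did not have. These rates may therefore not carry over to the real comparisons.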

Results

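The 21 libraries held between 24208569 (M11 replicate 3) and 90518872 (vehicle replicate 1) counts, and between 18307 and 20774 genes with a count. All groups had 3 libraries, and every level below is a mean with the SD of those 3. Replicates lay closest in the TGF-β1 group (median SD across genes of 0.0758 on the log2 scale) and farthest apart in the parental line (0.17). Parental replicate 1 carried 14% of its counts on a single ribosomal RNA-like gene, Gm42418, against at most 0.0918% in any other library, and its scaling factor was 0.839. Mitochondrially encoded genes took 1.8 to 3.42% of counts in the parental, M11 and M12 libraries, 0.861 to 1.09% in the empty vector and overexpression libraries, and 0.525 to 0.734% in the receptor libraries.

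ZBTB18 is a zinc finger repressor of transcription, and TGFBR2 is the receptor subunit that binds TGF-β. Zbtb18 (ENSMUSG00000063659.11, chromosome 1, 177442351 to 177450764 on build mm10) stood at 29.5 ± 1.4 CPM in the parental line and 25.1 ± 0.91 with empty vector. It reached 113 ± 9.6 with overexpression, 82.9 ± 6.5 and 95.2 ± 4.3 in the vehicle and TGF-β1 receptor groups, 34.7 ± 4.2 in M11 and 59.2 ± 10 in M12. Tgfbr2 (ENSMUSG00000032440.13, chromosome 9, 116084293 to 116175360) stood at 26.6 ± 0.44 CPM with empty vector, 1.74 ± 0.25 with ZBTB18 overexpression, and 588 ± 33 and 604 ± 17 in the vehicle and TGF-β1 receptor groups. It was 13.8 ± 0.81 CPM in the parental line, 21.4 ± 1 in M11 and 19.3 ± 1.8 in M12. The counts do not separate a construct's transcript from that of the cell's own gene.

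**Figure D1:**
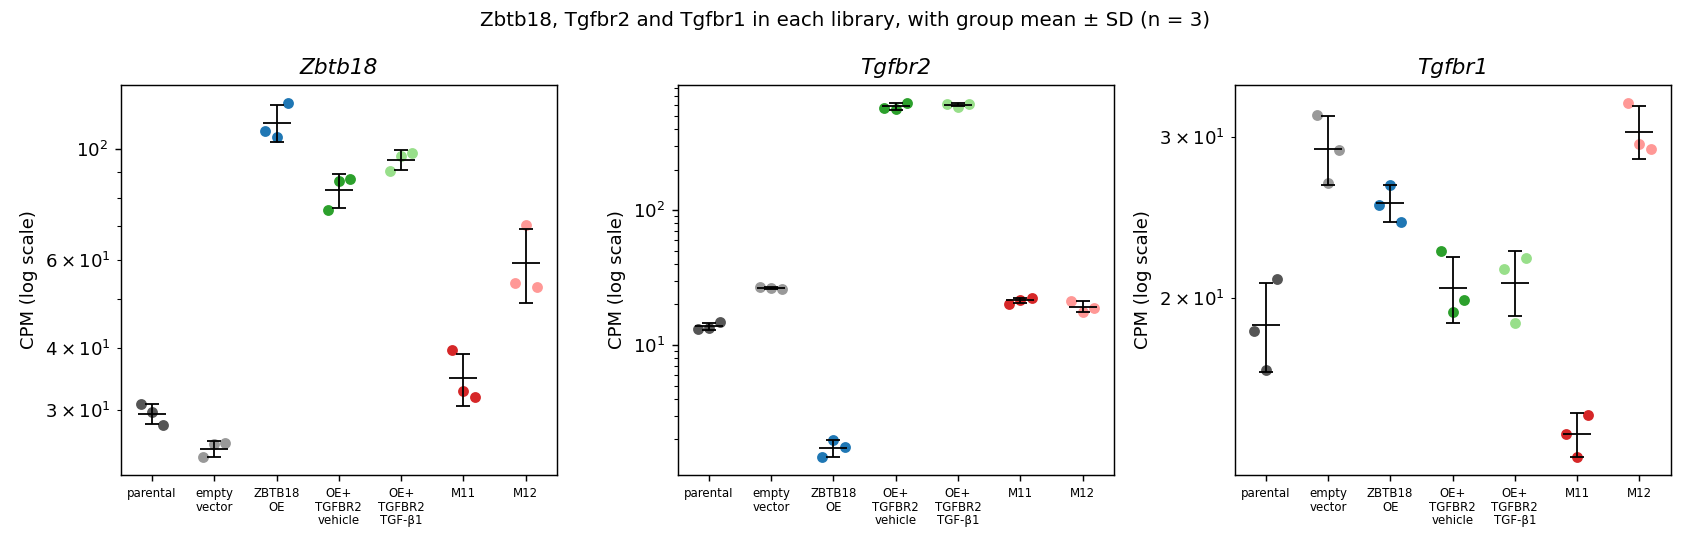
CPM of Zbtb18, Tgfbr2 and Tgfbr1 on a log axis in each library (points) of the 7 groups, with the group mean and SD (black, n = 3). Tgfbr2 sits lowest with ZBTB18 overexpression (1.74 CPM) and highest in the receptor groups (588 and 604), while the group means of Tgfbr1 lie between 14.2 (M11) and 30.4 (M12).

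The first comparison asked what ZBTB18 overexpression does to gene expression in E0771 cells. Zbtb18 itself was 4.5-fold higher than with empty vector (log2 fold change 2.17, SE 0.11, adjusted p = 3.35e-12). Tgfbr2 was 15.3-fold lower (-3.94, SE 0.1, adjusted p = 6.51e-17), while Tgfbr1, the partner receptor, was not past the threshold (25.4 ± 1.2 against 29.1 ± 2.5 CPM, adjusted p = 0.136). Parental Tgfbr2 was 13.8 CPM, below the 26.6 with empty vector and above the 1.74 with ZBTB18, so the size of its fall depends on the reference. Genes that TGF-β induces were lower as well: the matricellular gene Ccn2 fell from 5.49 to 0.888 CPM (-2.63), and the transglutaminase gene Tgm2 from 100 to 12.6 CPM (-2.99). Of 15432 genes tested, 4388 passed the threshold, 2153 higher and 2235 lower with ZBTB18. A fold of 2 or more was reached by 507 higher and 737 lower genes. The labels name a single overexpressing line and a single empty vector line, so other differences between these lines cannot be told from effects of ZBTB18. Calls leaned to one side on some chromosomes. They were 39 higher and 265 lower on chromosome 10, 19 and 239 on chromosome 13, and 221 and 26 on chromosome 19.

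Among the genes with the largest falls were Nsd1, a histone methyltransferase (11 ± 0.42 to 0.329 ± 0.19 CPM, log2 fold change -5.03), and Mmp2, a gelatinase (7.44 ± 1.2 to 0.28 ± 0.057 CPM, -4.73). The transporter gene Slc16a14 fell from 20 ± 4.4 to 0.0392 ± 0.02 CPM (-8.92), the potassium channel-interacting gene Kcnip1 from 9.95 to 0.0829 CPM (-6.85), and Nhsl2 from 5.24 to 0.0646 CPM (-6.29). Parp8 (27 to 0.848 CPM), Apobec1, the RNA-editing deaminase (5.25 to 0.167 CPM), and Fam49a (35.9 to 1.4 CPM) completed the 8 largest falls. The highest rises were in Dppa2, a pluripotency-associated gene (0.143 to 11.8 ± 0.75 CPM, 6.24), Pou2af1, a B-cell transcriptional coactivator (0.862 to 37.6 ± 3.8 CPM, 5.43), and the lysyl oxidase Loxl2, which crosslinks collagen (5.7 to 97.1 ± 16 CPM, 4.08). Ikzf2 rose from 0.883 to 14.1 CPM, the matricellular gene Ccn5 from 0.668 to 9.18 CPM (3.77), and Galnt15 from 0.646 to 6.24 CPM (3.29). The clustered protocadherins Pcdhgc4 (0.156 to 6.57 ± 6.4 CPM) and Pcdhgb1 (0.521 to 5.57 ± 1.5 CPM) share reads, and the first varied widely between replicates. The empty vector line stood apart from the parental line for some of these genes. Parental levels were 0.246 CPM for Slc16a14 and 0.0076 for Kcnip1, and 5.37 for Dppa2, 50.6 for Loxl2 and 2.59 for Galnt15, nearer to the overexpressing cells than to empty vector on the log2 scale. They were 12.3 CPM for Nsd1, 19.1 for Mmp2, 16.4 for Parp8, 4.24 for Apobec1 and 0.827 for Nhsl2, nearer to empty vector. In the receptor cells given vehicle, which also overexpress ZBTB18, Pou2af1, Ikzf2 and Galnt15 stood at 0.0525, 0.186 and 0.779 CPM, against 0.862, 0.883 and 0.646 CPM with empty vector. By a count chosen after the data had been seen, the parental mean lay nearer to the overexpressing cells in 242 of the 737 genes 2-fold lower and in 153 of the 507 genes 2-fold higher with ZBTB18, and the vehicle mean lay nearer to empty vector in 209 and 157.

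TGF-β response genes moved mainly down with ZBTB18: 22 of 31 tested members fell and 1, Nedd9, rose (1.11 against 0.134 CPM). The counts were the same when adjusted over the list alone. The median log2 fold change of the list was -0.83, and its adjusted p = 0.274 with an estimated correlation, so the list as a set did not pass. In empty vector against parental the list had a median of 0.44, so the empty vector reference itself stood above the parental line. Matrix proteases and inhibitors fell in 13 of 22 tested and rose in 2 (15 and 2 adjusted over the list alone, adjusted p = 0.274 with an estimated correlation), with Mmp19 (26.2 against 17.3 CPM) and Timp2 (402 against 280 CPM) as the higher ones. Notch pathway genes fell in 6 of 15 and rose in 2, the same when adjusted over the list alone (adjusted p = 0.274 with an estimated correlation). They included the ligand Jag2 (4.7 to 0.229 CPM) and the fringe gene Mfng (12.7 to 1.73 CPM) as lower, and Notch1 (64 to 104 CPM) as higher. Among 13 integrins 6 fell, such as Itgb4 (8.29 to 1.4 CPM) and Itga7 (4.01 to 0.655 CPM), and 2 rose, such as Itgb2 (1.28 to 3.58 CPM), with 7 and 3 adjusted over the list alone (adjusted p = 0.631 with an estimated correlation).

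Contractile genes fell in 16 of 40 and rose in 1 (17 and 1 adjusted over the list alone, adjusted p = 0.833 with an estimated correlation), with smooth muscle actin Actg2 going from 5.69 to 1.59 CPM. Without overexpression replicate 2 the 16 became 9. In the matrix list 11 of 27 fell, such as versican, Vcan (173 ± 34 to 33.2 ± 1.3 CPM), and 6 rose, such as Col6a3 (43.6 to 84.3 CPM), the same when adjusted over the list alone (adjusted p = 0.833 with an estimated correlation). The 6 became 3 and 2 without overexpression replicates 1 and 2. The mesenchymal list split 6 up and 7 down of 24 (6 and 8 adjusted over the list alone), and the adjusted p = 0.936 with an estimated correlation. S100a4 rose from 56 to 179 CPM in it, while the receptor gene Pdgfrb fell from 40.7 to 10.8 CPM. Without empty vector replicate 2 the 6 became 3. Axon guidance genes fell in 10 of 22 and rose in 4 (the same adjusted over the list alone, adjusted p = 0.634 with an estimated correlation). Ntn4 went from 2 to 0.217 CPM and Sema6d from 15.4 to 35.6 CPM. The 4 became 1 or 2 without empty vector replicate 1 or 2 or overexpression replicate 2 or 3. Among pathway components 8 of 27 fell and 1 rose (9 and 2 adjusted over the list alone, adjusted p = 0.631 with an estimated correlation); beside Tgfbr2 they included Smad2 (70.1 to 54.5 CPM), Smad4 (85.1 to 64.2 CPM) and Smad5 (128 to 85.7 CPM) as lower and Acvr2a (25.4 to 32.4 CPM) as higher. The 8 became 5 without overexpression replicate 1. The falls numbered 9 contractile, 6 matrix and 3 pathway component genes on log2(TPM + 1).

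Of the 6 ID family and neural target genes tested, Zeb1 fell (78.2 to 50.3 CPM, adjusted p = 3.01e-06) and the others did not pass; Id1, for example, was 89.3 ± 18 against 93.7 ± 17 CPM (adjusted p for the list 0.833 with an estimated correlation). The counts that rose and fell in the other lists were 2 and 7 of 25 epithelial genes, 5 and 12 of 36 cytokines and growth factors, 1 and 8 of 25 p53 targets and CDK inhibitors, 8 and 6 of 35 hypoxia and glycolysis genes, 9 and 2 of 38 sterol genes, 4 and 5 of 46 cell cycle genes, 4 and 4 of 24 NRF2 genes, 3 and 3 of 27 ATF4 genes, 6 and 8 of 27 immediate early genes, 1 and 5 of 23 YAP targets, 7 and 4 of 23 Wnt genes, 6 and 8 of 42 chromatin regulators, 7 and 6 of 26 metastasis-related genes, 3 and 5 of 13 mammary lineage genes and 5 and 2 of 18 ZBTB family genes. They were 1 and 4 of 47 ribosomal protein genes and 3 and 4 of 27 oxidative phosphorylation genes. Adjusted over the list alone the same lists gave 3 and 7, 5 and 13, 2 and 8, 8 and 6, 10 and 2, 2 and 3, 5 and 4, 3 and 3, 8 and 8, 1 and 5, 7 and 6, 6 and 8, 8 and 7, 3 and 7, 5 and 2, 0 and 1, and 3 and 4. Interferon-stimulated genes fell in 7 of 40 and MHC class I genes in 2 of 17 (7 and 0 adjusted over the list alone), while 1 of 12 heat shock genes, Hspa1b (8.59 ± 5.5 against 3.41 ± 1.9 CPM), rose, though not when adjusted over the list alone. None of the 10 mitochondrially encoded genes passed in edgeR. The adjusted p of these lists was 0.631 to 0.956 with an estimated correlation. Median, mean and test differed in sign for the epithelial, chromatin, mitochondrially encoded and ZBTB lists. Markers of other cell types moved in 2 of 6 tested for blood cells (Coro1a higher, Cd14 lower), 4 of 9 for endothelium, 3 of 8 for fibroblasts (Col3a1 higher, Gsn and Pdgfrb lower) and 2 of 5 for lung epithelium, with adjusted p = 0.833, 0.631, 0.833 and 0.318 with an estimated correlation; adjusted over the list alone they were 2, 4, 3 and 3. Leaving out 1 library moved several of these counts. Without empty vector replicate 1, 2 or 3 the hypoxia genes that rose numbered 5, 5 and 4, and without overexpression replicate 2 or 3 they numbered 4 and 5. The 12 cytokines that fell became 7 and 6 without empty vector replicate 2 or 3, and 5, 4 and 7 without overexpression replicate 1, 2 or 3; the 5 that rose became 3 without empty vector replicate 2 or overexpression replicate 3. The 9 sterol genes became 4 without empty vector replicate 3 and 3 without overexpression replicate 1. The 8 chromatin regulators that fell became 5, 5 and 4 without empty vector replicate 1, 2 or 3 and 3 without overexpression replicate 2, and the 6 that rose became 3 without empty vector replicate 2 or overexpression replicate 2. The 8 immediate early genes that fell became 5 without empty vector replicate 2 or 3 or overexpression replicate 2 or 3, and the 6 that rose became 3 without empty vector replicate 1. The 7 interferon-stimulated genes became 4 without empty vector replicate 3 or overexpression replicate 3, the 7 Wnt genes that rose 4 without overexpression replicate 2, and the 5 mammary genes that fell 3 without empty vector replicate 2 or overexpression replicate 3. The 4 cell cycle genes that rose became 2 without empty vector replicate 2 or overexpression replicate 2 or 3, and the 5 that fell became 3 without any library other than empty vector replicate 2. The 4 ribosomal protein genes became 1 without empty vector replicate 2 or overexpression replicate 3 and 2 without overexpression replicate 2, and the 4 oxidative phosphorylation genes that fell became 2 without empty vector replicate 1 or overexpression replicate 3. On log2(TPM + 1) the total fell from 4388 to 2837 genes, and the falls numbered 5 cytokines, 3 epithelial, 4 immediate early, 3 cell cycle, 3 mammary and 2 oxidative phosphorylation genes. Chromatin regulators then gave 2 up and 2 down, and 5 hypoxia genes rose.

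**Figure D2:**
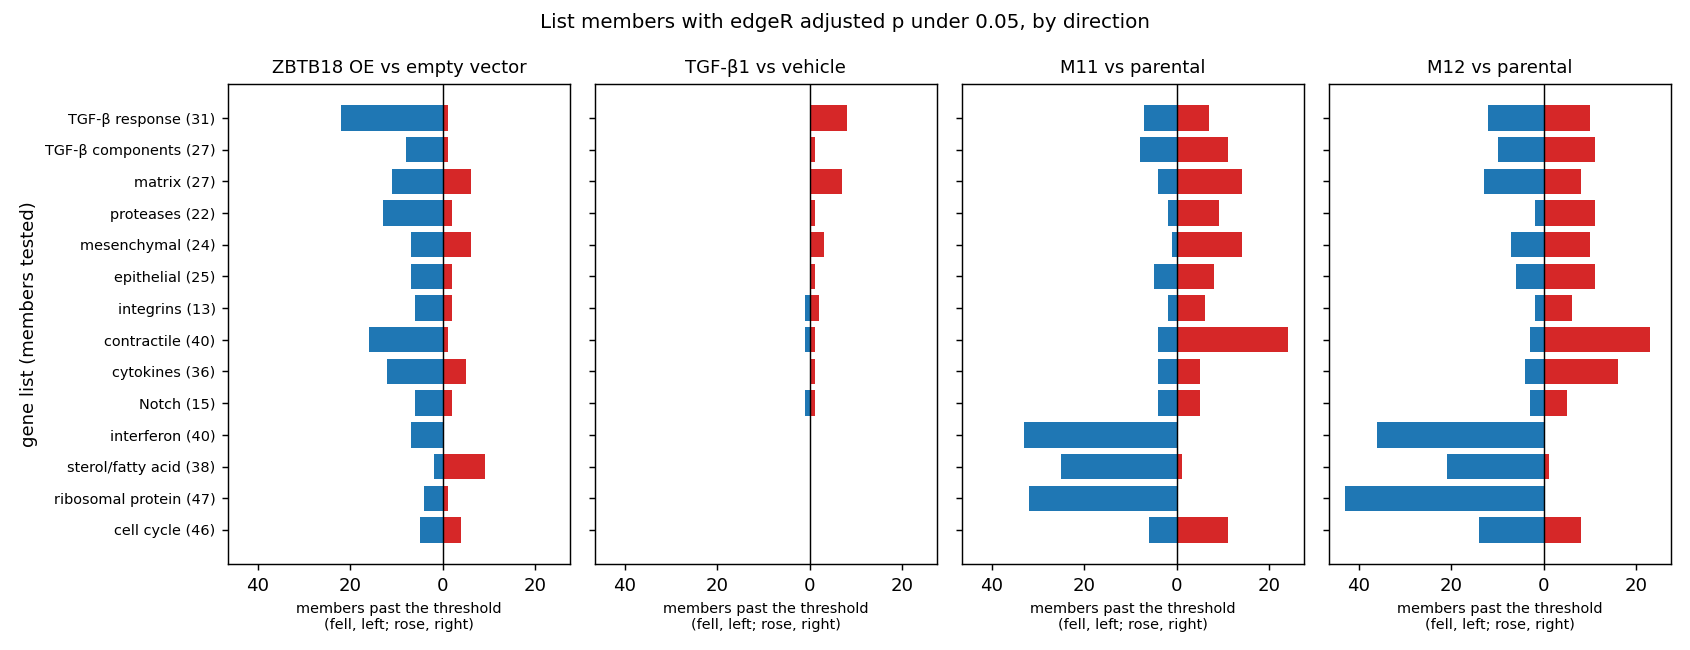
Number of members of 14 gene lists past the threshold in 4 comparisons, with those that fell to the left of 0 and those that rose to the right; the number tested stands beside each name. TGF-β response genes fell in 22 of 31 with ZBTB18 overexpression and rose in 8 with TGF-β1; the M12 cell cycle split of 8 up and 14 down became 18 up and 2 down on log2(TPM + 1), and M12 matrix (8 and 13) and TGF-β response (10 and 12) turned to 9 and 7 and to 12 and 8.

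The next comparison asked what TGF-β1 does in overexpressing cells with the inducible receptor. Col7a1, the anchoring fibril collagen, rose from 19.6 ± 3.3 to 92.1 ± 4.6 CPM (log2 fold change 2.24, SE 0.19, adjusted p = 1.46e-06), Col1a1, fibrillar collagen I, from 10 ± 1.8 to 38.8 ± 6.7 CPM (1.95, SE 0.3, adjusted p = 0.00164), and Ccn2 from 3.82 ± 1.3 to 14.7 ± 3.1 CPM (1.96, SE 0.37, adjusted p = 0.01). The related matricellular gene Ccn4 rose from 16.2 to 65.2 CPM (2.01) and Skil, which encodes a SMAD co-repressor, from 24.9 to 61.1 CPM (1.30). The number of genes past the threshold was 295, with 194 higher and 101 lower; 51 and 21 changed 2-fold or more. Zbtb18 (0.20, adjusted p = 0.433) and Tgfbr2 (0.04, adjusted p = 0.929) were not among them.

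Other rises were in Tnnt2, cardiac troponin T (0.406 to 15.9 ± 1.8 CPM, log2 fold change 5.20), Rap1gap2 (0.765 to 7.65 CPM, 3.29) and Acsbg1, an acyl-CoA synthetase gene (3.95 to 19 CPM, 2.28). Ctsw, a cathepsin gene, had 3 reads over the vehicle group and 1164 with TGF-β1, a ratio of 402 with a counting interval of 137 to 1950. The genes that fell 2-fold or more and met the rule numbered 7: Ptgds, prostaglandin D synthase (10.8 ± 3.4 to 2.56 ± 0.73 CPM), Zfp428 (20 to 7.86 CPM), the integrin gene Itgb7 (9.15 to 4.01 CPM), the neuronal tubulin Tubb3 (35.2 to 16 CPM), the adhesion gene Mcam (18.3 to 8.42 CPM), Cnst (28 to 13 CPM) and Adhfe1 (23.2 ± 6.3 to 11.2 ± 2.5 CPM, adjusted p = 0.0477). Of 41 calls of named genes in this comparison, 21 held on log2(TPM + 1), 13 held on log2(TPM + 0.1), and 21 to 32 held without 1 library; Adhfe1, Ccn2, Itgb7, Ptgds and Tubb3 were among those lost in at least 1 alternative.

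TGF-β response genes rose in 8 of 31 tested and in 13 when adjusted over the list alone, and the others did not pass. This was the 1 list past the threshold as a set (adjusted p = 0.0404 with an estimated correlation, and 0.0383 with a replicate block). Pdlim7 (34.2 to 57.1 CPM) and Ldlrad4 (3.76 to 6.25 CPM) were among its members. In the matrix list 7 of 27 rose and 11 did when adjusted over the list alone (adjusted p = 0.647 with an estimated correlation), with Lamb1 at 4.12 against 1.66 CPM and Col5a2 at 0.621 against 0.201 CPM. Without TGF-β1 replicate 1 the 7 became 4. Chromatin regulators rose in 4 of 42, and in 9 when adjusted over the list alone (adjusted p = 0.853 with an estimated correlation): the DNA methyltransferases Dnmt3a (39.9 to 59.6 CPM) and Dnmt3b (4.71 to 8.28 CPM), Hmga2 (110 to 153 CPM) and Kdm1a (138 to 181 CPM). The 4 became 2 without any of the TGF-β1 libraries or vehicle replicate 2, and 1 without vehicle replicate 1. Among integrins Itgb3 (10.3 to 19.3 CPM) and Itgb5 (98.2 to 150 CPM) rose, and in the mesenchymal list Msn (1110 to 1540 CPM) and Fstl1 (98.2 to 144 CPM) did, with adjusted p = 0.853 for both lists with an estimated correlation. The Notch ligand gene Jag2 fell from 0.853 to 0.38 CPM while Notch4 rose from 4.29 to 11.5 CPM. On log2(TPM + 1) the rises numbered 5 of the response genes, 4 of the matrix genes, 1 of the mesenchymal genes and 0 of the chromatin regulators, and 0 integrins passed. Median, mean and test differed in sign for the YAP, fibroblast, blood cell, lung and cytokine lists.

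The count of genes in this comparison depended on the method: DESeq2 called 594, the 6 libraries alone 1343, no filter 633, and log2(TPM + 1) 78. Leaving out each library gave 71 (vehicle replicate 2), 101 (vehicle replicate 1), 110, 120 and 126 (TGF-β1 replicates 1, 3 and 2) or 183 (vehicle replicate 3). Replicates of the same number resembled each other, with a correlation of residuals of 0.274 to 0.581, and at most -0.0345 otherwise. Residuals are deviations from the group mean, so high values for the same number press the other values down. Libraries of different numbers reached 0.507 in M11 against parental, and the labels state no pairing, so pairing is not established. A replicate block within the 2 groups called 248 genes.

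The genes that moved with ZBTB18 and with TGF-β1 overlapped in opposite directions more than independent calls would. Of the 2235 genes lower with ZBTB18, 65 were higher with TGF-β1 against 28.1 expected (ratio 2.31, Fisher's exact p = 1.83e-11), and of the 2153 higher, 30 were lower against 14.09 expected (ratio 2.13, p = 3.53e-05). In the same direction the numbers were 18 lower in both against 14.63 (Fisher's exact p = 0.322) and 17 higher in both against 27.07 (Fisher's exact p = 0.0365). Ccn4 (log2 fold change -2.87 with ZBTB18 and 2.01 with TGF-β1), Ccn2 (-2.63 and 1.96), Notch4 (-1.93 and 1.42), Col7a1 (-1.03 and 2.24), Inava (-1.49 and 1.33) and Skil (-1.26 and 1.30) fell with the first and rose with the second. Lpar2, Mcam, Prph, Itgb7, Xdh and Tmem62 did the reverse, for example Mcam at 0.97 and -1.13. As sets, the genes lower and the genes higher with ZBTB18 did not pass with TGF-β1 (camera adjusted p = 0.0704 and 0.223 with an estimated correlation, adjusted over 12 tests of ZBTB18 sets). Nor did those changed 2-fold or more (adjusted p = 0.525 and 0.227). Across genes the correlation of fold changes was -0.122 (Pearson) and -0.145 (Spearman), and genes are not independent replicates.

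**Figure D3:**
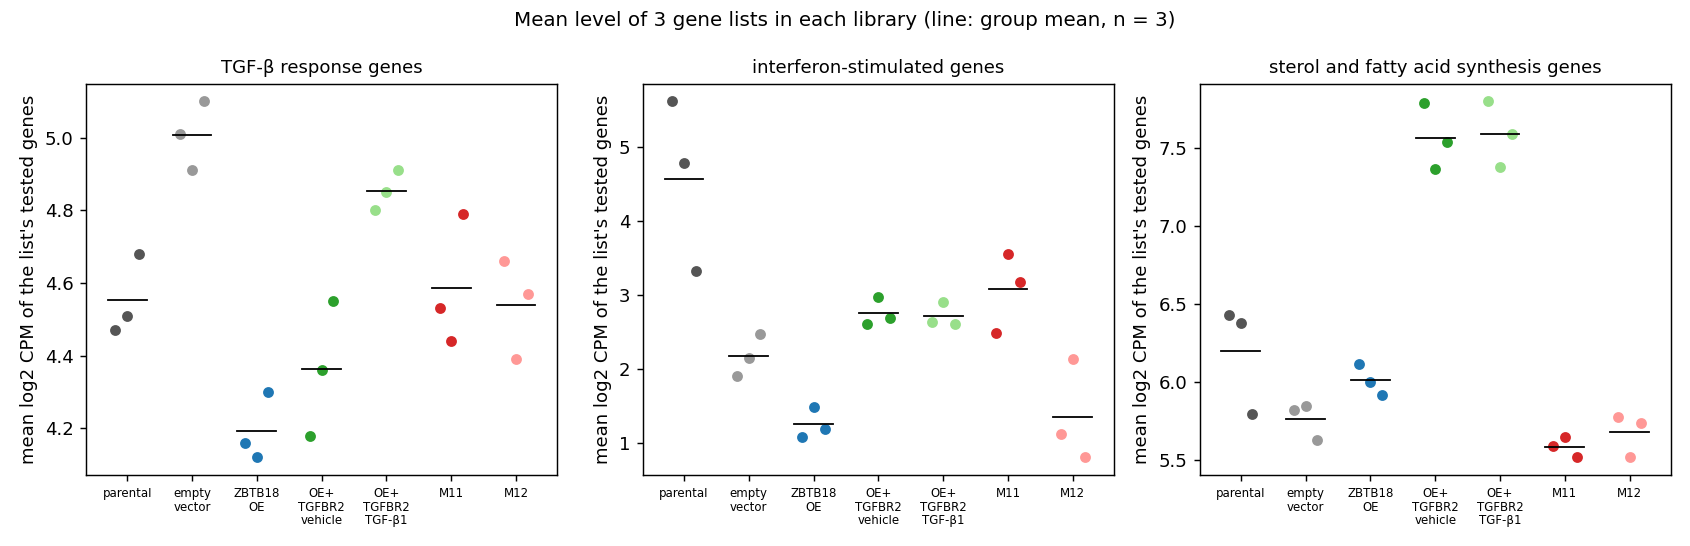
Mean log2 CPM of the tested TGF-β response, interferon-stimulated and sterol synthesis genes in each library (points), with the group mean as a line (n = 3). TGF-β response genes lie at 4.12 to 4.3 with ZBTB18 overexpression and 4.8 to 4.91 with TGF-β1; interferon genes spread from 3.32 to 5.62 in the parental line; sterol genes lie at 7.37 to 7.8 in the receptor groups.

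M11 was compared with the parental line to see what changed in cells from a lung metastasis. Col6a3, a collagen VI chain, was 387 ± 16 CPM against 2.33 ± 0.57 (log2 fold change 7.37, SE 0.23, adjusted p = 2.76e-14), and Actg2 29.3 ± 2.4 against 0.399 ± 0.17 (6.20). Zbtb18 did not pass (34.7 ± 4.2 against 29.5 ± 1.4 CPM, adjusted p = 0.0825). Tgfbr2 was 1.55-fold higher (0.63, adjusted p = 5.48e-06) and Tgfbr1 1.32-fold lower (-0.40, adjusted p = 0.00348). Col6a3, Actg2 and Tgfbr2 also stood above the parental line with empty vector, which is not a metastasis line. Tgfbr2 was at 26.6 CPM with empty vector, 21.4 in M11 and 13.8 in the parental line. Tgfbr1 went the other way from M11, at 29.1 CPM with empty vector against 18.7 in the parental line. The threshold was passed by 6288 genes, 3207 higher and 3081 lower, with 1083 and 701 at 2-fold or more. On log2(TPM + 1), where the median of all genes lay 0.17 higher, 3999 genes were higher and 1153 lower, so that 77.6% of calls were higher against 51% with TMM; the 6 libraries alone gave 4175 genes.

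Pik3ap1, an adaptor of B-cell receptor signalling, had 1 read over the parental libraries and 678 in M11, a ratio of 765 with a counting interval of 137 to 30200. Lrmp (0.0417 to 22.1 ± 2.2 CPM) and Hcls1 (0.0359 to 11.8 ± 0.77 CPM) rose with it, as did Slc16a14 (0.246 to 23.4 CPM), the glycine decarboxylase gene Gldc (0.0493 to 5.07 CPM) and Faim2 (0.195 to 13.5 CPM). The peptidase gene Dpp4 had 3 reads in M11 and 1363 in the parental line, a ratio of 403 with a counting interval of 138 to 1960. Tex19.2, a germline gene (16.8 to 0.14 CPM, log2 fold change -6.90), Serpina11 (5 to 0.0944 CPM), Ablim1 (8.34 to 0.2 CPM) and Rasgrp2 (26.5 to 1 CPM) also fell. So did Oas2 (16.6 ± 12 to 0.312 ± 0.04 CPM) and Ifi27l2a (25 ± 11 to 0.871 ± 0.12 CPM), whose parental levels varied, and Hist1h1d, whose parental level of 9.79 ± 16 CPM rested on parental replicate 1.

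In M11 interferon-stimulated genes fell in 33 of 40 tested (35 adjusted over the list alone), but as a set they did not pass (adjusted p = 0.677 with an estimated correlation). Without parental replicate 1 the 33 became 18, and without M11 replicate 1 they became 21. Within MHC class I, Psmb8 (21 to 51.6 CPM) and Psmb9 (3.94 to 11.5 CPM) rose, 4 members in all of 17, while 2 fell (the same adjusted over the list alone, adjusted p = 0.833 with an estimated correlation), and log2(TPM + 1) gave 7 up and 1 down. Contractile genes rose in 24 of 40 and fell in 4 (25 and 4 adjusted over the list alone, adjusted p = 0.677 with an estimated correlation). Leaving out parental replicate 1, 2 or 3 made the 4 into 2, and leaving out M11 replicate 1 or 2, or taking log2(TPM + 1), into 1. Mesenchymal genes rose in 14 of 24 and fell in 1 (15 and 1 adjusted over the list alone, adjusted p = 0.229 with an estimated correlation). Prrx1 went from 14.8 to 110 CPM and S100a4 from 64.6 to 318 CPM. In the matrix list 14 of 27 rose and 4 fell (15 and 4 adjusted over the list alone, adjusted p = 0.677 with an estimated correlation). Col3a1 went from 37.2 to 721 CPM and Col1a1 from 4.7 to 0.992 CPM. With empty vector these genes stood at 172 and 1.51 CPM.

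Sterol and fatty acid synthesis genes fell in 25 of 38 in M11 and rose in 1, the same when adjusted over the list alone (adjusted p = 0.677 with an estimated correlation), with Cyp51 going from 119 to 33.2 CPM and Idi1 from 90.2 to 31.9 CPM. Ribosomal protein genes fell in 32 of 47 (38 adjusted over the list alone, adjusted p = 0.677 with an estimated correlation) but in 7 on log2(TPM + 1). The 32 became 14 without parental replicate 1, and 13 without parental replicate 2 or without M11 replicate 3. Oxidative phosphorylation genes split 2 up and 13 down of 27 with TMM (3 and 14 adjusted over the list alone, adjusted p = 0.784 with an estimated correlation) and 7 up and 2 down on log2(TPM + 1). The 13 became 4 without parental replicate 2 and 7 without M11 replicate 3. Blood cell markers rose in 2 of 6, Cd79a (0.433 to 2.83 CPM) and Coro1a (0.575 to 2.25 CPM), and fell in 3, among them Cd14 and Lyz2, with adjusted p = 0.954 with an estimated correlation. Fibroblast markers rose in 4 of 8 and fell in 1, and endothelial markers rose in 4 of 9 and fell in 2, the same adjusted over the list alone (adjusted p = 0.677 for both with an estimated correlation); on log2(TPM + 1) the endothelial markers gave 1 up and 1 down of 4 tested. TGF-β response genes split 7 up and 7 down of 31 with TMM and 13 up and 5 down on log2(TPM + 1) (8 and 7 adjusted over the list alone, adjusted p = 0.954 with an estimated correlation).

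M12 was compared with the parental line for the same purpose. Wnt5a, a Wnt ligand, had 0 reads in the parental libraries and 729 in M12, at least 221-fold higher, and Col8a1, a collagen gene, went from 0.0378 to 38.4 ± 6.8 CPM (log2 fold change 9.99, SE 0.53, adjusted p = 3.27e-10). Zbtb18 was 2.01-fold higher than in the parental line (1.00, SE 0.11, adjusted p = 9.86e-08), Tgfbr2 1.4-fold higher (0.49, adjusted p = 8.03e-05) and Tgfbr1 1.63-fold higher (0.70, adjusted p = 5.37e-06). Both receptor genes also stood higher with empty vector (26.6 and 29.1 CPM) than in the parental line (13.8 and 18.7 CPM), while Zbtb18 did not. The threshold was passed by 7737 genes, 3847 higher and 3890 lower, with 1428 and 941 at 2-fold or more. On log2(TPM + 1) the median of all genes lay 0.20 higher, and 4987 genes were higher and 1416 lower (77.9% of calls higher, against 49.7% with TMM).

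Pik3ap1 had 2321 reads in M12 against 1 in the parental line (ratio 2110, counting interval 379 to 83600), and the ADP-ribosyltransferase gene Art3 had 1820 against 1 (ratio 1660, counting interval 297 to 65500). Hcls1 (22.2 ± 5 CPM), Ccbe1 (24.5 ± 7.6 CPM), Gldc (15.9 CPM) and Lrmp (12.9 CPM) had parental levels of 0.0359, 0.0625, 0.0493 and 0.0417 CPM. The antiviral gene Oas2 had 3 reads in M12 and 1923 in the parental line, a ratio of 704 with a counting interval of 240 to 3410. Ifi27l2a went from 25 ± 11 to 0.0343 CPM, Samd9l from 88.3 ± 35 to 0.368 CPM, Usp18 from 42.1 ± 36 to 0.323 CPM, Ifi44 from 36 ± 30 to 0.29 CPM, Oas3 from 55.6 ± 44 to 0.589 CPM and Trim30a from 13.8 ± 7.6 to 0.146 CPM, all of them interferon-inducible; Dpp4 fell from 11.9 to 0.0947 CPM.

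Interferon-stimulated genes fell in 36 of 40 in M12 (37 adjusted over the list alone, adjusted p = 0.874 with an estimated correlation). Cytokine and growth factor genes rose in 16 of 36 and fell in 4, the same when adjusted over the list alone (adjusted p = 0.874 with an estimated correlation), the neutrophil chemokine Cxcl2 going from 0.167 to 29 CPM, and Ptgs2, the inducible cyclooxygenase, from 0.358 to 8.61 CPM. Proteases and inhibitors rose in 11 of 22 and fell in 2 (11 and 4 adjusted over the list alone, adjusted p = 0.874 with an estimated correlation), among them Adam19 (0.14 to 33.5 CPM) and Adam8 (4.72 to 32.8 CPM). Contractile genes rose in 23 of 40 and fell in 3, the same when adjusted over the list alone (adjusted p = 0.874 with an estimated correlation). Among epithelial genes 11 of 25 rose, such as Krt18 (0.0643 to 3.01 CPM) and Epcam (0.222 to 1.72 CPM), and 6 fell (12 and 6 adjusted over the list alone, adjusted p = 0.874 with an estimated correlation). Mesenchymal genes split 10 up and 7 down of 24, the same adjusted over the list alone (adjusted p = 0.874 with an estimated correlation), with Snai2, an EMT transcription factor, at 1.34 against 0.0759 CPM and S100a4 at 15.4 against 64.6 CPM. In the matrix list 8 of 27 rose and 13 fell, the same adjusted over the list alone (adjusted p = 0.986 with an estimated correlation), while log2(TPM + 1) gave 9 up and 7 down; its median and test were negative and its mean positive. The falls numbered 2 epithelial and 4 mesenchymal genes on log2(TPM + 1).

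Blood cell markers rose in 5 of 6 tested in M12, the same when adjusted over the list alone (adjusted p = 0.874 with an estimated correlation): Cd68 (4.85 to 36.9 ± 28 CPM), Cd79a (0.433 to 8.02 ± 0.36 CPM), Coro1a and S100a8 were among them. Endothelial markers rose in 5 of 9 and fell in 2 (5 and 3 adjusted over the list alone, adjusted p = 0.874 with an estimated correlation), but 0 rose and 1 fell of 4 tested on log2(TPM + 1). Fibroblast markers rose in 3 of 8 and fell in 2 (the same adjusted over the list alone, adjusted p = 0.986 with an estimated correlation). The blood cell list held 26 genes, of which 6 were among the genes tested. The mean log2 CPM of those tested was 2.1 to 2.59 in M12 and 0.24 to 0.86 in the parental libraries. Sterol genes fell in 21 of 38 and rose in 1 (the same adjusted over the list alone), and ribosomal protein genes fell in 43 of 47 (43 adjusted over the list alone) but in 16 with 1 higher on log2(TPM + 1); both lists had adjusted p = 0.874 with an estimated correlation. Hypoxia and glycolysis genes split 4 up and 17 down of 35 with TMM (4 and 18 adjusted over the list alone, adjusted p = 0.874 with an estimated correlation) and 5 up and 4 down on log2(TPM + 1). The 17 became 9 without M12 replicate 2, and the 21 sterol genes became 13 on log2(TPM + 1). TGF-β response genes split 10 up and 12 down of 31 with TMM, the same adjusted over the list alone, and 12 up and 8 down on log2(TPM + 1) (adjusted p = 0.986 with an estimated correlation). Their median and test were negative and their mean positive.

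The lists of genes changed in M11 and in M12 overlapped: 2172 genes were higher in both against 799.5 expected (odds ratio 13.2), 1948 lower in both against 776.6 (odds ratio 9.21), and 269 went in opposite directions. Both comparisons use the same parental libraries, so the overlap was also set against simulated unchanged groups compared with those libraries; 19 of 20 draws called 0 genes in either comparison, so they could share none, and the remaining draw shared 61 higher and 75 lower. The correlation of fold changes was 0.7437 against a simulated mean of 0.332 and highest of 0.699. The covariance, to which shared libraries add the same amount with or without real effects, was 0.949 against a simulated mean of 0.0447 and highest of 0.163. The 3 parental libraries cannot be split with 2 or more on each side, so part of the excess may come from the shared controls. Faim2, Hcls1, Lrmp, Gldc, Pik3ap1 and Col6a3 had the largest joint rises, and Dpp4, Oas2 and Ifi27l2a were among the largest joint falls. The small nuclear RNA Rn7sk met the same rule, but its parental level rested on parental replicate 1, at 358 CPM against 1.39 and 0.738 in the others.

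A further question was whether genes lower with ZBTB18 than with empty vector are higher in the metastasis lines. Fewer such genes were found than independent calls would give: 374 against 464.5 in M11 (ratio 0.805, Fisher's exact p = 2.08e-07) and 467 against 557.2 in M12 (ratio 0.838, p = 1.47e-06). Genes higher with ZBTB18 and lower in the line numbered 262 against 429.8 in M11 (ratio 0.61, Fisher's exact p = 1.54e-24) and 340 against 542.7 in M12 (ratio 0.626, Fisher's exact p = 1.39e-29). Genes that moved the same way were in excess, with 811 lower in both against 446.2 and 887 higher in both against 447.4 for M11, and 918 against 563.4 and 1005 against 536.7 for M12. Among genes changed 2-fold or more in both comparisons the opposite-direction ratios were above 1: for genes lower with ZBTB18 they were 2.17 in M11 (Fisher's exact p = 3.3e-15) and 2.51 in M12 (Fisher's exact p = 3.93e-31). For genes higher with ZBTB18 they were 1.35 (Fisher's exact p = 0.102) and 1.33 (Fisher's exact p = 0.0593). The same-direction ratios at 2-fold were larger, 5.88 for lower and 5.62 for higher genes in M11 and 4.56 and 4.8 in M12. In the opposite-direction sets at 2-fold, the parental level lay nearer to the overexpressing cells than to empty vector in 75 of 112 genes lower with ZBTB18 and higher in M11, 107 of 171 for M12, and 23 of 31 and 21 of 41 in the reverse sets. The same held in 19 of 197 and 17 of 200 genes lower and higher in both for M11, and in 22 of 205 and 36 of 225 for M12. The parental libraries also enter the M11 and M12 calls that define these sets. The sets therefore select for the parental level, and the contrast between them cannot tell whether the empty vector line stood apart. Slc16a14 (log2 fold change -8.92 with ZBTB18 and 6.60 in M11, at 0.246 CPM in the parental line and 20 CPM with empty vector), Actg2, the B-cell factor Pax5, Spata13, Ugt1a7c and Clip4 were lower with ZBTB18 and higher in M11. Acpp, Pax5, Clip4, Ugt1a7c, Cfap57 and Map2k6 were so for M12, with Acpp at -4.59 and 3.50. In the other direction stood Tex19.2 (2.23 and -6.90), Dppa2, Slc22a18, Unc13a, Osmr and Aqp1 for M11, and Gas7 (1.76 and -4.44), Sardh, Rab3il1, S100a4, Aqp1 and Tenm4 for M12. As a set, the genes lower with ZBTB18 were lower in M11 and M12 (camera adjusted p = 0.0281 in each, with an estimated correlation and adjusted over the same 12 tests), and the genes higher with ZBTB18 were higher (adjusted p = 0.0281 in each). Of those changed 2-fold or more with ZBTB18, the higher genes were higher in M11 and M12 (camera adjusted p = 0.0304 and 0.0281) and the lower genes did not pass (adjusted p = 0.441 and 0.671).

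M11 and M12 also differed from each other, in 5474 genes, 2730 higher and 2744 lower in M11, with 651 and 742 at 2-fold or more. Slc16a14 (23.4 against 0.152 CPM), Tafa5 (16.4 against 0.279 CPM), Gas7 (29.1 against 0.502 CPM) and Rufy4 (16.1 against 0.304 CPM) were the highest in M11. Art3 had 0 reads in M11 and 1820 in M12, at least 490-fold higher in M12, and Col8a1 (0.122 against 38.4 CPM), Tex19.2 (0.14 against 23.9 CPM) and Ccbe1 (0.194 against 24.5 CPM) were higher there too. Matrix genes were higher in M11 in 18 of 27 and lower in 3 (19 and 3 adjusted over the list alone), Col6a1 at 632 against 76.6 CPM and Col6a2 at 274 against 17.2 CPM. The list gave adjusted p = 0.666 with an estimated correlation and 0.013 with a replicate block within the 2 groups. Replicates of the same number resembled each other here too (residual correlation 0.248 to 0.467, at most 0.13 otherwise). The labels state no pairing, and the block called 6038 genes.

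Interferon-stimulated genes were higher in M11 than in M12 in 25 of 40 (29 adjusted over the list alone, adjusted p = 0.973 with an estimated correlation). Usp18 stood at 7.32 against 0.323 CPM. The 25 became 15 without M11 replicate 2 or M12 replicate 1 and 16 without M12 replicate 3. Blood cell markers were lower in M11 in 5 of 6, and in 6 when adjusted over the list alone (adjusted p = 0.166 with an estimated correlation), Cd68 at 9.25 ± 3.4 against 36.9 ± 28 CPM. Cytokine and growth factor genes were lower in M11 in 12 of 36 and higher in 5 (14 and 5 adjusted over the list alone, adjusted p = 0.973 with an estimated correlation). The 12 became 7 on log2(TPM + 1). Cxcl2 stood at 0.432 against 29 CPM and Ccl5 at 6.74 against 1.62 CPM. Zbtb18 was 1.7-fold lower in M11 (-0.77, adjusted p = 8.49e-06). With the 6 libraries alone 3525 genes passed in place of 5474.

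The empty vector line differed from the parental line in more genes than in any other comparison: 8944 passed, 4462 higher and 4482 lower, with 813 and 1701 at 2-fold or more. Among the highest were the potassium channel genes Kcnmb1, with 1026 reads against 0 in the parental libraries, at least 254-fold higher, and Kcnip1, with 1591 against 1 (ratio 1180, counting interval 212 to 46700). Slc16a14 (0.246 to 20 CPM) and Sema5a (0.227 to 8.2 CPM) rose with them. Oas2 (16.6 ± 12 to 0.146 CPM), Ifi44 (36 ± 30 to 0.63 CPM) and Ifi27l2a (25 ± 11 to 0.462 CPM) fell, as did Rn7s1 from a parental level of 698 ± 1200 CPM, whose SD exceeded its mean. Rn7s1 lost its call in limma-voom and with the 6 libraries alone, and its fall was smaller without parental replicate 1. Interferon-stimulated genes fell in 38 of 40 (38 adjusted over the list alone), while chromatin regulators rose in 31 of 42 and fell in 1 (31 and 2 adjusted over the list alone), contractile genes rose in 29 of 40 and fell in 1 (the same adjusted over the list alone), and 7 of 10 mitochondrially encoded genes fell (8 adjusted over the list alone); each list had adjusted p = 0.471 with an estimated correlation. Id1 (45.3 to 93.7 CPM), Id2, Id3 and Tgfbr2 (13.8 to 26.6 CPM) were higher, and Zbtb18 did not pass (adjusted p = 0.0656). On log2(TPM + 1) the median of all genes lay 0.29 higher, with 6593 genes higher and 1626 lower (80.2% of calls higher, against 49.9% with TMM). With TMM, contractile and ribosomal protein genes moved the same way against the parental line in M11, M12 and empty vector. The medians were 0.49, 0.41 and 0.62 for contractile genes and -0.36, -0.45 and -0.76 for ribosomal protein genes. No label separates the vector from a difference in culture or library preparation.

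Overexpressing cells with the receptor, doxycycline and vehicle were compared with overexpressing cells without it, a contrast in which the receptor, doxycycline and any difference in culture stand together. Tgfbr2 was 339-fold higher (588 ± 33 against 1.74 ± 0.25 CPM, log2 fold change 8.40, SE 0.12, adjusted p = 9.39e-23), and Zbtb18 1.36-fold lower (-0.45, adjusted p = 0.00162). The threshold was passed by 5986 genes, 3006 higher and 2980 lower, with 987 and 808 at 2-fold or more. Sterol and fatty acid synthesis genes rose in 35 of 38, the same adjusted over the list alone (adjusted p = 0.287 with an estimated correlation), Mvd, the mevalonate decarboxylase gene, going from 18.6 to 130 CPM, Lss, lanosterol synthase, from 37 to 220 CPM and Fdft1, squalene synthase, from 22.4 to 148 CPM. Hypoxia and glycolysis genes rose in 22 of 35 and fell in 1 (25 and 1 adjusted over the list alone, adjusted p = 0.287 with an estimated correlation). Car9 went from 1.02 to 30.7 CPM and Adm from 9.77 to 63.7 CPM. Id1 (89.3 to 32.3 CPM), Id2 (15.5 to 0.716 CPM) and Id3 (64.9 to 7.23 CPM) fell (adjusted p of the list 0.287 with an estimated correlation). Interferon-stimulated genes rose in 28 of 40 and fell in 1 (29 and 1 adjusted over the list alone, adjusted p = 0.79 with an estimated correlation). Fibroblast markers rose in 5 of 8 and fell in 1, the same adjusted over the list alone (adjusted p = 0.52 with an estimated correlation), and mitochondrially encoded genes fell in 7 of 10 (9 adjusted over the list alone, adjusted p = 0.79 with an estimated correlation), with medians of 1.39 and -0.74.

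Ptgds (0.195 to 10.8 ± 3.4 CPM) rose in the receptor cells, and Col13a1 had 939 reads against 2 (ratio 388, counting interval 107 to 3210). Pou2af1, which was higher with ZBTB18 overexpression than with empty vector (0.862 CPM), fell from 37.6 ± 3.8 to 0.0525 CPM, and Sema6d (35.6 to 0.138 CPM) and Fam110c (8.13 to 0.0426 CPM) fell as well. TGF-β response genes rose in 12 of 31 and fell in 7 (12 and 8 adjusted over the list alone, adjusted p = 0.79 with an estimated correlation). Tgm2 went from 12.6 to 54.3 CPM and Ccn2 from 0.888 to 3.82 CPM. The 7 became 4 without vehicle replicate 1, and log2(TPM + 1) gave 10 up and 2 down. The mesenchymal homeobox gene Prrx1 fell from 104 to 3.21 CPM, and the collagens split, Col3a1 falling from 279 to 17.6 CPM and Col1a1 rising from 0.99 to 10 CPM.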

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

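The tests of chance placement on chromosomes, of copy number outside chromosome 1, of the interferon genes and of the sterol genes were chosen only after those results had been seen; the splits of the libraries, the GC content and length correction and the copy number test of chromosome 1 were written before. No group had more than 3 libraries, so none was tested for outlying samples.

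M11 and M12, both compared with the parental line, differed from each other, and the difference itself was tested by comparing the lines directly. The direct comparison called 5474 genes, and 269 genes changed in opposite directions in the 2 lines with the direct comparison past the threshold. Among the genes selected by the naming rule, those higher than parental in M11 and lower in M12 had log2 fold changes, M11 minus M12, of 5.86 for Tafa5, 5.85 for Gas7, 5.72 for Rufy4, 4.37 for S100a4, 3.53 for Egr3, 3.04 for Col6a1, 2.99 for Tet1, 2.75 for Itgb4, 2.6 for Psmb9, 2.25 for Ntn1, 1.28 for Nlrc5, 1 for Pfkfb4 and 0.78 for Zeb1. Those lower in M11 and higher in M12 had -0.5 for Rest, -1.1 for Tgfbr1, -1.52 for Rnd1, -2.12 for Cd14, -2.15 for S100a8 and -7.41 for Tex19.2. S100a4, for example, had 2.30 in M11 and -2.07 in M12, and Tgfbr1 had -0.40 and 0.70.

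Each comparison of 3 libraries with 3 gives 10 splits, too few for a share under 0.05. In each of the 7 comparisons 1 of 10 splits, the real one, called as many genes as the real one. The real values and the highest of the other splits were 4388 and 0 for ZBTB18 overexpression, 295 and 0 for TGF-β1, 6288 and 1062 for M11, 7737 and 1764 for M12, 5474 and 301 for M11 against M12, 8944 and 1 for empty vector against parental, and 5986 and 0 for vehicle against overexpression. The highest other splits in M11 and M12 put parental replicates 1 and 2 with replicate 2 of the metastasis line.

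Genes of whole chromosomes shifted together in the comparisons of cell lines. The largest chromosome medians of log2 fold change were -0.29 on chromosome 13 with ZBTB18 overexpression, 0.40 on chromosome 1 in M11 and 0.39 on chromosome 1 in M12, against at most 0.02 with TGF-β1. Chance placement was argued against, since 1000 shuffles of genes among chromosomes gave at most 0.12, and so was a trend with GC content or gene length as the whole cause, since its removal left at least 0.28. A difference in copy number may underlie the shift of chromosome 1 in M11 and M12: in each of 3 equal bins of expression at least 61.9% of chromosome 1 genes were higher than in the parental line, narrowly above the 60 set beforehand. Empty vector against parental also had a chromosome 1 median of 0.18, beyond the 0.15 of its shuffles. In its low bin 40.4% of chromosome 1 genes were higher. Across chromosomes that share ran from 24.2% (chromosome 19) to 44.5% (chromosome 18) in the same comparison, so a low share there was not particular to chromosome 1. M11 against M12 had -0.02. Each of these lines was set against the same parental libraries, so a change in the lines cannot be told from one in the parental cells. Of the other shifts beyond the shuffles with ZBTB18 overexpression and in M11 and M12, that of chromosome 18 in M11 argued against a change of the whole chromosome, since 38.5% of its genes were higher in the middle bin (SE 4.4). Of the remaining 15, 3 had over 60% of genes on the side of the shift in each bin and 12 lay lower in at least 1 bin, down to 50% on chromosomes 1 and 12 with ZBTB18 and 50.2% on chromosome 6 in M12, so copy number stays open for those. DNA was not measured, so this stays a hypothesis.

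Interferon-stimulated genes were lower in M11 than in the parental line in 33 of 40. Variation of the parental cultures is a candidate explanation: without parental replicate 1 the number fell to 18, and the lowest parental library had a mean log2 CPM of 3.32 for the list, below the highest M11 library at 3.56. The list was also lower than in the parental line in M12 and with empty vector, which is not a metastasis line. Its median log2 fold change was -1.83 in M11, -3.14 in M12 and -2.69 with empty vector. These comparisons share the parental libraries, so a raised parental level cannot be told from a lower level in each line. A lasting difference between the lines remains open, as the design names M11 as a separate line and no further cultures were measured.

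Sterol synthesis genes were higher in the vehicle receptor cells than in overexpressing cells without the receptor in 35 of 38. Signalling that the ligand would raise further stays open: the median log2 fold change of the list with TGF-β1 was 0.02, but -0.09 to 0.14 without 1 library, on both sides of the 0.1 set after the data had been seen. An ATF4 response to doxycycline was argued against by a rise in 6 of 27 ATF4 genes with 6 lower. A difference of culture or library batch could not be separated from the groups: the median of 1.67 is what either would give, and no label names a batch. The receptor without added ligand and doxycycline itself also stay open and untested.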

How the results depend on the processing

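The replicate block within the 2 groups compared was chosen after the data had been seen; the other alternatives were set before. The cause of the differences below was not tested.

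Across all alternatives with a value, 667 of 916 calls of a named gene held in every one, and 5 named genes changed sign. All of these came with TPM: on log2(TPM + 1) and log2(TPM + 0.1), Smad2 in M12 gave 0 and 0, and in empty vector against parental Myc gave 0.03 and 0.03, Eed 0.11 and 0.11, Ltbp3 0.02 and 0.02 and Zbtb7b 0.17 and 0.18. The median of all genes moved up by 0.20 in M12 and 0.29 in empty vector on log2(TPM + 1), more than any of these values, so relative to the other genes none of the 5 turned. It moved up by 0.17 in M11 as well, but lay between -0.036 and 0.028 in the comparisons without parental libraries. TPM was taken without further scaling between libraries, and parental replicate 1 carried 14% of its counts on Gm42418. Whether that moved the medians or the list counts on TPM was not tested.

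The count of genes changed by TGF-β1, 295, was the least stable: 633 with no filter, 594 with DESeq2, 1343 with the 6 libraries alone, 78 on log2(TPM + 1), 53 on log2(TPM + 0.1) and 71 to 183 without 1 library. For ZBTB18 overexpression TPM gave 2837 and 2835 in place of 4388. With the 6 libraries alone M11 gave 4175 in place of 6288 and M11 against M12 3525 in place of 5474. The other counts stayed within 1.5 times in every alternative.

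Lists past the threshold depended on the test. In place of 0 with an estimated correlation, a preset correlation and fry gave 6 and 15 for ZBTB18 overexpression, 9 and 22 for M11, 5 and 19 for M12, 4 and 9 for M11 against M12, 9 and 26 for empty vector, and 6 and 20 for vehicle against overexpression; for TGF-β1 they gave 4 and 2 in place of 1. A block within the 2 groups gave 1 for M11 against M12.

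Ratios of ZBTB18 overlaps with the metastasis lines in opposite directions went from under to over 1 among genes changed 2-fold or more in both: 2.17 and 1.35 for M11 and 2.51 and 1.33 for M12, where 1.35 and 1.33 did not pass Fisher's exact test and the same-direction ratios were larger. At 3 libraries a group the simulated data gave back 58.2 to 68.7% of 1.5-fold changes.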

Other observations

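The test here was written before its result was seen.

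Genes moved in the same direction with ZBTB18 overexpression and in M11 and M12, with a correlation of fold changes across genes of 0.173 and 0.15. One hypothesis was that shared shifts of whole chromosomes produced it. On genes with a position, removing the median of each chromosome took the correlation with M11 from 0.172 to 0.165. With M12 it went from 0.145 to 0.138, so such shifts added little to these correlations. The test had little room to show more: M11 with M12 gave 0.745 before and 0.748 after, although their chromosome 1 medians were 0.4 and 0.39. Whether the shifts feed the same-direction excess among called genes was not tested. Genes are not independent replicates, and no other explanation was tested.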
